A study of Mus musculus with 4 samples.

How the data were processed

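Gene expression was measured in whole normal skeletal muscle of wild type mice on a mixed background of 129S4/SvJae and C57BL/6, on 1-colour Affymetrix arrays, with 1 array per sample and 4 samples. The series also covers rhabdomyosarcomas started from Pax7-expressing muscle progenitor cells and pleomorphic sarcomas started by Cre virus injected into muscle, per its design text. Those tumours were not analysed here. Per the labels' protocols, total RNA came from either a column kit for fibrous tissue or a phenol reagent followed by columns, and biotin-labelled targets were made with a linear amplification kit. The labels give no extraction route for a single sample.

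The deposited values are log2 expression values per probe set, made by the authors with robust multi-array averaging (RMA) in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA corrects the background of each array, brings the arrays to 1 distribution and summarises the probes of a probe set. It compresses differences near the background and near the brightest values, so small folds at both ends are understated. The log2 scale was read from the values, which ran from 2.80 to 14.76 with array medians of 7.26 to 7.30. Which other arrays were normalized together with these 4 is not given in the sources used here. No centring of genes was seen.

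The files held 22690 probe sets. Of these, 64 were control probe sets, which were left out of the tests. The platform annotation named 1 gene for 20380 probe sets, several for 691 and none for 1555, and 13 control probe sets carried a gene name. Symbols were updated through Entrez identifiers against the gene table of the GRCm38.p6 assembly, used for names alone, and 29 probe sets with 1 gene kept the older symbol. No gene was named from a probe set with several genes. Where a gene had several probe sets, the one with the highest mean over the 4 samples stood for it, which left 12393 genes. Of these, 4956 had several probe sets, and in 37 of those the probe sets disagreed in direction by more than 0.5 on the log2 scale each way. No further normalization and no filter on dim genes was applied. No column of per-sample values was left unused.

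All 4 samples formed 1 group, normal muscle, so the labels gave no contrast between study groups. Their titles carry a prefix, nm or skm, whose meaning the labels do not give. Before the data were examined, this prefix was fixed as a possible batch of collection or extraction, and the skm minus nm difference was planned as a test of it, together with the gene lists, the rule for named genes and the alternatives. Each gene's difference was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 arrays against 2, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and borrowed 3.51 from the other genes. Errors given with a difference are standard errors of that fit with n = 2 per prefix, and SDs are over the 4 samples. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

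The 29 gene lists held muscle fibre types, muscle regulators, metabolism, stress and signalling pathways, the circadian clock, position genes, sex-linked and strain genes, and markers of other cell types that muscle can hold. Of their 315 entries, 280 had a usable probe set. Lists were compared between prefixes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Each list's median SD was set against 10000 random lists of the same size drawn from 20 bins of mean level. Control probe sets were read per array. An outlying sample was called with Dixon's ratio at its 95% critical value.

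The named genes followed a fixed rule. For the spread, they were the 20 genes with the largest SD among genes with a mean at or above the median. For the prefix, they were the genes past the threshold without overlap, and, since fewer than 5 passed in either direction, also the 5 highest and 5 lowest by moderated t. Up to 4 members of each list by the size of the difference or SD were added, with Pax7, Myod1, Ptch1 and the sex-linked genes always named. Trp53 belonged to the rule and had no probe set of 1 gene, so it was not analysed here, and not every gene of the rule is reported here.

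The alternatives set in advance were quantile normalization of the 4 arrays, centring each array on its median, a filter at the median level, the mean of all probe sets of a gene, leaving out probe sets prone to cross-hybridization, each sample left out in turn, an intensity trend in eBayes, probe sets in place of genes, an estimated correlation in camera, fry in place of camera, and the range in place of the SD. The added alternatives, chosen after seeing the data, were fry's test in either direction, a threshold of 0.10, and set tests on further fatty acid synthesis genes. The gene test was tested on simulated data of 12393 genes, 2 arrays against 2, with 100 genes changed at each size. It called 56% of the genes changed by 1 on the log2 scale and 97% of those changed by 2, and 10 unchanged genes. The simulated errors were independent between genes and drawn from the fitted spread, so these shares need not hold for the data. In the data, Glycam1 at -3.73 and Dbp at 2.93 missed the threshold, while Slc25a25 at 2.00 passed. A gene that was not called may therefore still have changed. In the simulated data, camera called the 1 list that was shifted and 0 of 27 unchanged lists. The simulated noise had no correlation between genes, so this does not test camera on lists whose members move together.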

Results

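The data were 4 arrays of normal muscle from wild type mice, a single group with replicates 1 to 4 titled nm7, nm8, skm4 and skm5. In the series, normal muscle stands beside sarcomas of 2 origins, which were not analysed here. The question left to these samples is how far normal muscle differed between samples and which gene groups carried the difference. Values were log2 RMA expression values of 12393 genes, with 1 probe set per gene. The arrays had medians of 7.26 to 7.30, and no pair held the same values throughout.

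Genes of lymphocytes, of the circadian clock and of fat metabolism were among the 20 with the largest SD over the samples, of those with a mean at or above the median. Glycam1, a ligand of L-selectin on lymph node venules, had the largest SD, 2.52 (n = 4), with values of 9.69 in nm7, 10.14 in nm8, 4.59 in skm4 and 7.77 in skm5. Ms4a4b, a T cell membrane protein, had an SD of 2.14, Ptprc, the pan-leukocyte phosphatase CD45, 1.51, Ltb, a lymphoid cytokine, 1.27, and Coro1a and Cd53, both leukocyte genes, 1.20 and 1.07. Among clock genes, the SD was 1.73 for Dbp, a clock-driven transcription factor, 1.15 for Per1 and 0.96 for Per3, both repressors of the clock. Among genes of fat, Lep, which encodes leptin, had an SD of 1.34 and Acly, which makes acetyl-CoA for lipid synthesis, 1.05.

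The other genes chosen by their SD included stress response genes. Ddit4, an inhibitor of mTORC1, had an SD of 1.55, Chac1, a glutathione-degrading enzyme, 1.26, and Gadd45g, a growth arrest gene, 1.24. The SD was 1.21 for Limd2, 1.16 for Slc25a25, a mitochondrial carrier of ATP-Mg and phosphate, 1.14 for Angptl7, 1.09 for Dysf, the membrane repair protein dysferlin, 1.08 for Paip1, a translation factor, and 1.03 for Sncg. Without nm7 the SD of Chac1 was 0.40, and without skm4 that of Glycam1 was 1.26, that of Ms4a4b 0.99 and that of Ptprc 0.67. Leaving out nm7 also took Gadd45g to 0.58 and Paip1 to 0.55, leaving out skm4 took Limd2 to 0.69, Coro1a to 0.59 and Cd53 to 0.62, and leaving out nm8 took Sncg to 0.60. With the mean of all probe sets of a gene, the SD was 0.28 for Per3, 0.30 for Paip1, 0.68 for Acly, 0.69 for Limd2 and 1.11 for Ms4a4b. Over all genes, the median SD was 0.191, and 741 genes (5.98%) had a range over 1, which is 2-fold. That number was 429 without skm4 and 291 among genes at or above the median level.

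Sarcomere genes of fast and slow fibres differed in their spread. The 11 measured fast fibre genes, such as Myh4, the myosin heavy chain of type IIb fibres, and Pvalb, a calcium buffer of fast fibres, had SDs of 0.01 to 0.10. Their median SD of 0.03 lay at percentile 0 of random lists of like level, whose median was 0.11. All of them read between 14.02 and 14.76, and 14.76 was the highest value on any array, so a difference among them could be compressed. The 13 slow fibre genes had a median SD of 0.41, at percentile 100, against 0.13 in random lists. Myh7, the slow myosin heavy chain, read 12.92 in nm7, 12.46 in nm8, 12.83 in skm4 and 11.64 in skm5, and Myl3, a slow light chain, 12.95, 12.19, 13.00 and 12.19 in the same order. Centred on each gene's mean, the slow list had medians of 0.28, -0.23, 0.37 and -0.42, so as a list it split each prefix and not the prefixes from each other. Of its 13 members, 3 had no overlap between the prefixes, among them Csrp3 at -1.03 ± 0.27 and Casq2 at -0.67 ± 0.14. The list's median skm minus nm difference was -0.04, and 0 of 13 members passed the test over all genes or adjusted over the list alone. That median rested on every sample: it was 0.23 without nm7, -0.32 without nm8, -0.41 without skm4 and 0.31 without skm5.

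**Figure D1:**
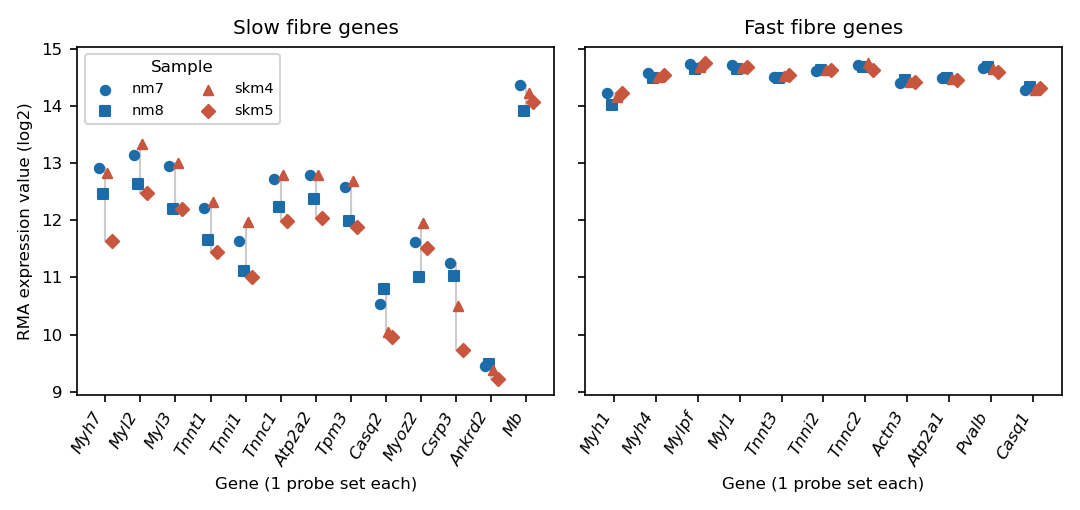
Log2 RMA values of the 13 slow fibre genes (left) and 11 fast fibre genes (right) in the 4 normal muscle samples, with 1 point per sample and a grey line over the range of each gene. Fast fibre genes lie between 14.02 and 14.76 with SDs of at most 0.10, while slow fibre genes have a median SD of 0.41.

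In all, 14 of the 29 lists had a median SD at or above percentile 95 of random lists, and 3 lay at or under percentile 5. Besides the slow fibre genes, the lists at the top were clock genes, lymphocyte, adipocyte and keratinocyte markers, immediate early, fasting and cell cycle genes, tendon, Schwann cell, macrophage and endothelial markers, p53 pathway genes and hindlimb position genes. Leaving out 1 sample took 7 of these lists under percentile 95: p53 pathway genes to 51.8, tendon markers to 63.2 and endothelial markers to 84.4 without nm8, macrophage markers to 48.3 and cell cycle genes to 87.5 without skm4, hindlimb genes to 82.3 without nm7 and 92.7 without skm4, and p53 pathway genes to 80.1 and keratinocyte markers to 58.3 without skm5. Keratinocyte markers had a median SD of 0.71 against 0.23 in random lists, and of 0.22 against 0.20 without skm5. Dsp, which encodes desmoplakin, read 4.12, 4.48 and 4.32 in nm7, nm8 and skm4 and 8.33 in skm5, and Lor, which encodes loricrin of the cornified layer, 5.95, 6.44, 6.41 and 8.77. Tendon markers were lowest in nm8, where Chad, a cartilage and tendon matrix protein, read 6.76 against 8.31 in nm7, 8.64 in skm4 and 7.71 in skm5. Mbp, a myelin protein, read 10.74 in skm4 and 12.09 in skm5. The lists at the bottom were fast fibre genes, glycolysis genes with a median SD of 0.06 (percentile 0.73), and Hedgehog pathway genes with 0.11 (percentile 1.42). Glycolysis genes read between 11.75 and 14.60, so differences among the brightest of them could be compressed too. Glycolysis genes lay above percentile 5 without nm8 (5.48) or skm5 (12.0), and Hedgehog genes without nm8 (6.07), skm4 (11.2) or skm5 (8.99).

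Between the title prefixes, 4 genes passed the test, and 2 of them belong to the circadian clock. Arntl, the activator of the clock also called Bmal1, was 3.46-fold lower in the skm samples (-1.79 ± 0.12 SE on the log2 scale), and its repressor Per3 was 3.17-fold higher (1.67 ± 0.12). Dysf was 3.70-fold higher (1.89 ± 0.11) and Slc25a25 rose from a mean of 7.66 to 9.66 (SE of the difference 0.13). These genes, 3 higher and 1 lower, passed limma's test over 12393 genes, each at an adjusted p = 0.047. The next adjusted p, 0.0506, was shared by 130 genes, 55 higher and 75 lower, so the number called rested on the threshold. At an unadjusted p under 0.05 there were 2918 genes where 620 would be expected, and 54.4% of genes had no overlap between the prefixes where chance gives 33.3%.

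Genes that missed the threshold at an adjusted p of 0.0506 made up the rest of the largest moderated t values. On the low side in skm were Trim12a at -1.61 ± 0.13, Lpxn, a leukocyte adaptor protein, at -1.91 ± 0.17, Neu2, a cytosolic sialidase, at -1.44 ± 0.14 and the predicted gene Gm15510 at -1.62 ± 0.16. Gm15510, at a mean of 4.19 in skm, and Lpxn, at 4.68, were dim there, so the size of both differences is limited by the background. On the high side were Smyd1, a methyltransferase of striated muscle, at 1.42 ± 0.12 and Tpsab1, a mast cell tryptase, at 1.33 ± 0.12. With the mean of all probe sets in place of the brightest, Per3 differed by 0.45 (adjusted p = 0.127), Smyd1 by 0.80 and Trim12a by -0.80. The count of 4 became 1026 among genes at or above the median level, 1110 with an intensity trend, and 0 without nm7, without nm8 or without skm4 against 15 without skm5.

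All 12 measured clock genes had no overlap between prefixes, and 11 of them, 7 higher and 4 lower in skm, passed when adjusted over the list alone, while 1 rose and 1 fell over all genes. Adjusted over the list alone, Per2 rose from a mean of 4.55 to 7.56 (SE of the difference 0.34), Dbp by 2.93 ± 0.27 (7.64-fold) and Per1 by 1.88 ± 0.31 (3.67-fold), all of them driven by Arntl with its partner Clock. Per2 read 4.03 in nm8, as dim as the control probe sets of TrpnX, a bacterial transcript, at 3.57 to 4.05 in that sample, so the size of its rise is limited by the background. Clock and Npas2, the partners of Arntl, differed by -1.11 ± 0.14 and -1.30 ± 0.14, and Nr1d1, the member that did not pass, by 0.60 ± 0.31. These last 3 were singled out after their values were seen. The list's median absolute difference was 1.27 against 0.22 in random lists of like level (percentile 100). Since its members went both ways, camera, which looks for a shift in 1 direction, gave an adjusted p = 0.079, and 0.83 with an estimated correlation. It was 0.00078 among genes at or above the median level, but only 8 of the 12 members were left there. Their median difference was 1.09, against 0.77 for all 12, so that value is not for the same list. It was 0.17 with the mean of probe sets and 0.1 with quantile normalization. The median difference was 0.64 without nm7, 1.03 without nm8, 0.64 without skm4 and 0.90 without skm5. In fry's test for change in either direction, added after the data were seen, the adjusted p was 0.0075. That test called 11 lists, and its adjusted p was lower for glycolysis genes (0.00099) and interferon-induced genes (0.0017). Its value therefore does not single out the clock genes.

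**Figure D2:**
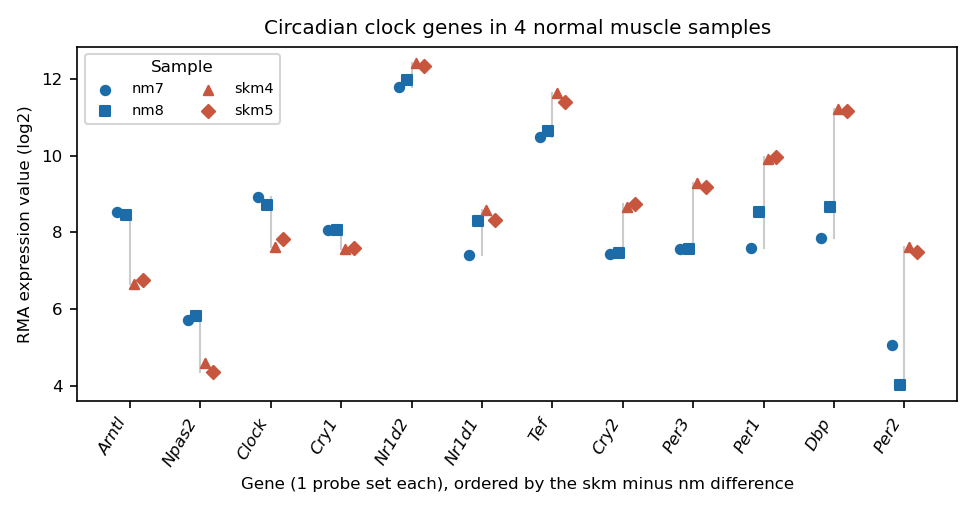
Log2 RMA values of the 12 measured circadian clock genes in the 4 normal muscle samples, with 1 point per sample and a grey line over each gene's range, ordered from the lowest to the highest skm minus nm difference. Arntl and its partners are lower in both skm samples and Per1, Per2, Per3 and Dbp are higher.

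Lymphocyte markers fell in skm as a list (camera, adjusted p = 0.00024), and the call was lost at an adjusted p = 0.91 with an estimated correlation and at 0.22 with fry. Of 10 measured members, 0 passed over all genes and 8, all lower, passed adjusted over the list alone, with a list median of -1.34. Cd3g, a chain of the T cell receptor complex, differed by -2.49 ± 0.32, Ms4a1, the B cell antigen CD20, by -2.33 ± 0.65, Ptprc by -2.18 ± 0.63 and Cd79b, a chain of the B cell receptor, by -1.70 ± 0.25. Cd3g at 4.90 and Ms4a1 at 4.85 were dim in skm4, where differences are compressed. In skm5, Ms4a1 read 6.97 and Ptprc 9.3 against nm means of 8.24 and 10.5, so skm4 carried much of both differences. The centred list medians were 0.53 in nm7, 0.72 in nm8, -0.97 in skm4 and -0.14 in skm5. Among genes at or above the median level 2 of the 10 were left, with a median of -1.42 and an adjusted p = 0.29, and without nm8 the members adjusted over the list alone numbered 4. Macrophage markers (median -0.11, camera adjusted p = 0.55) and neutrophil markers (median -0.02, adjusted p = 1.0) had 0 members past either test, with Mrc1, the mannose receptor, at -0.49 ± 0.14 and S100a8, a calcium-binding protein of neutrophils, at -0.26 ± 0.27. Without skm5, macrophage markers had a median of -0.47 and 5 of 11 passed adjusted over the list alone (camera, adjusted p = 0.08).

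Genes of oxidative phosphorylation and the citrate cycle rose in skm as a list (camera, adjusted p = 0.036), as did embryonic sarcomere and denervation genes (adjusted p = 0.036). Both calls were lost at an adjusted p = 0.83 with an estimated correlation. The 17 oxidative genes had a median difference of 0.24, with 13 positive and 0 past the gene test over all genes or adjusted over the list alone. Their median was 0.13 with the mean of probe sets, 0.17 with quantile normalization and 0.15 without nm8. Atp5b, the beta subunit of ATP synthase, differed by 0.48 ± 0.12 and Cox6a2, a muscle subunit of cytochrome oxidase, by 0.44 ± 0.12. Of the 11 embryonic and denervation genes, 0 passed over all genes and 2 rose when adjusted over the list alone, Tnnt2, the cardiac and embryonic troponin T, by 0.68 ± 0.14 and Chrna1, a subunit of the acetylcholine receptor, by 0.55 ± 0.13. Ankrd1, a stretch-responsive muscle gene, stood at 1.09 ± 0.49 and Chrnd, another receptor subunit, at 0.41 ± 0.16. Ankrd1 overlapped between the prefixes, at 7.89 in nm7, 6.59 in nm8, 7.88 in skm4 and 8.79 in skm5, so its size rested on single samples. Without nm7, nm8 or skm5, or without cross-hybridizing probe sets, 0 of the 11 passed adjusted over the list alone, and without skm4 1 did. Without nm8 both lists had an adjusted p of 0.082, and without skm5 of 0.08; quantile normalization ended the oxidative call (0.1), and the filter (0.25, with 5 of the 11 genes left), the mean of probe sets (0.054), leaving out cross-hybridizing probe sets (0.062) and fry (0.099) ended the embryonic call.

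Among muscle regulators, 0 of 13 passed over all genes and 2 passed adjusted over the list alone. Myod1, which drives the muscle programme, rose by 1.24 ± 0.16, and Sdc4, a surface proteoglycan of satellite cells, fell by 0.82 ± 0.12 by that test. Pax7, the transcription factor of satellite cells and the gene whose cells gave rise to tumours elsewhere in the series, differed by -0.31 ± 0.12 (adjusted p = 0.20), and Myog, which acts in differentiation, by 0.73 ± 0.22. Ptch1, the Hedgehog receptor, differed by -0.64 ± 0.16 (adjusted p = 0.105), and 0 of 7 Hedgehog genes passed either test. Of 8 measured genes of the p53 pathway and RAS, 0 passed either test, with the cell cycle inhibitor Cdkn1a at 0.60 ± 0.26. Of 15 cell cycle genes, 0 passed over all genes and 3 fell when adjusted over the list alone, including the proliferation marker Mki67 by 1.81 ± 0.34 and Top2a, a topoisomerase of dividing cells, by 1.30 ± 0.16. Both were dim in skm4, Mki67 at 5.05 and Top2a at 5.28, so the size of these differences may be limited by the background. Mki67 read 6.89 in nm7, 7.61 in nm8, 5.05 in skm4 and 5.82 in skm5, in the order of the lymphocyte list's medians. The medians of the adipocyte and interferon lists had this order too, so it does not single out lymphocytes. Camera gave an adjusted p of 1.0 for the regulators, 0.90 for Hedgehog, 0.69 for p53 and RAS and 0.14 for cell cycle genes, the last 0.03 without skm5, where 5 passed adjusted over the list alone, and 0.22 without nm8, where 1 did.

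Adipocyte markers had 0 of 10 members past the test over all genes and 4 adjusted over the list alone, all lower in skm. Lep fell by 2.26 ± 0.26 (4.80-fold), Pparg, the regulator of adipocytes, by 0.94 ± 0.19, Scd1, a fatty acid desaturase, by 0.82 ± 0.21 and Adipoq, which encodes adiponectin, by 0.56 ± 0.16. Camera gave an adjusted p = 0.079 for the list, which was 0.046 without nm7 and 0.0041 without skm5, but 0.13 without nm8, where 1 of 10 passed adjusted over the list alone, and 0.33 without skm4, where 2 did and the median was -0.11. Interferon-induced genes had 5 of 9 adjusted over the list alone, 1 higher and 4 lower, and 0 over all genes, with Ifit1 at -0.97 ± 0.20, Gbp2 at -0.87 ± 0.13 and Irf7, a transcription factor of the response, at 0.80 ± 0.17 (camera, adjusted p = 0.079), and 2 adjusted over the list alone without nm8. Endothelial markers went both ways, with 3 higher and 2 lower of 10 adjusted over the list alone and 0 over all genes. Pecam1, an adhesion molecule, rose by 1.31 ± 0.16 and Ramp2, an adrenomedullin receptor component, by 0.99 ± 0.12, while Kdr, a VEGF receptor, fell by 0.58 ± 0.12 by that test (camera, adjusted p = 0.54), and without nm7 or without skm5 2 passed it. Immediate early genes also went both ways, with 5 of 14 adjusted over the list alone, where Egr1 fell by 1.41 ± 0.26 and Nr4a1 rose by 1.21 ± 0.16, and 0 over all genes (camera, adjusted p = 0.90); the 5 were 3 without nm7 and 8 without nm8.

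Fasting and glucocorticoid response genes had 5 of 13 members past the test adjusted over the list alone, 3 higher and 2 lower, and 0 over all genes (camera, adjusted p = 0.27). Mt2, a metallothionein, rose by 1.29 ± 0.17, while Fkbp5, a glucocorticoid target, stood at 0.79 ± 0.33. Without nm7 or without nm8 1 of the 13 passed adjusted over the list alone, and without skm4 3 did. Keratinocyte markers (camera, adjusted p = 0.079) had 0 of 8 past either test, and their p was 1.9e-07 without skm4, where 6 of 8 passed adjusted over the list alone, and 0.81 without skm5. Erythroid markers (camera, adjusted p = 0.079) had 0 of 4, with Alas2, an enzyme of haem synthesis, at 1.09 ± 0.33. Alas2 read 8.28 in nm7, 8.10 in nm8, 8.77 in skm4 and 9.79 in skm5, so skm5 carried much of its difference. The erythroid median was 0.34, and 0.32 to 0.37 with a sample left out. Of the position genes, Hoxc8 fell by 0.96 ± 0.12 adjusted over the list alone, the 1 of 10 hindlimb and posterior genes to do so (3 passed without skm5), and 0 of 9 forelimb and anterior genes passed (camera, adjusted p = 1.0 for both lists), with 0 of either list over all genes.

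The remaining lists had 0 members past either test. Camera's adjusted p was 0.15 for 11 glycolysis genes, where Pgam2, a muscle phosphoglycerate mutase, stood at 0.39 ± 0.12, and 0.49 for 10 genes of the unfolded protein response, where Hspa5, the chaperone BiP, stood at -0.58 ± 0.14. It was 0.25 for 8 tendon markers, whose median was 0.37. Without nm7 it was 0.00026 for them, with 3 past the test adjusted over the list alone, and without nm8 their direction turned (median -0.02, adjusted p = 0.82). It was 0.55 for 13 slow fibre genes and, without skm4, 0.0061 with 3 adjusted over the list alone. For 6 Schwann cell and nerve markers it was 0.55, and 0.034 without skm4, with 2 adjusted over the list alone, while without skm5 their direction turned (median -0.18, adjusted p = 0.71) and 3 passed that way. It was 0.45 for 10 fibroblast markers and 1.0 for 8 smooth muscle markers and for 11 fast fibre genes. The 4 measured sex-linked genes gave 0.77, with Y-linked Eif2s3y between 9.67 and 9.93, Kdm5d between 7.19 and 7.78 and Uty between 7.11 and 7.72 in the 4 samples, and Xist, the RNA of X inactivation, between 6.96 and 7.29. The 2 genes with known variants between the parent strains gave 1.0, with Nnt, a mitochondrial transhydrogenase, at 0.47 ± 0.20 and Casp4, an inflammatory caspase, at -0.53 ± 0.21. Adjusted over the list alone, both passed with the mean of probe sets or without cross-hybridizing probe sets, and 1 passed without nm7 or without skm5. By the same count, 2 oxidative and 2 slow fibre genes passed with the filter, 1 slow fibre gene with the mean of probe sets, 1 Hedgehog gene with the filter or without skm5, 1 gene of p53 and RAS without skm4, 1 erythroid marker with quantile normalization or without skm4, and 1 tendon marker and 2 genes of the unfolded protein response without cross-hybridizing probe sets. The last list had 1 with quantile normalization or the filter. Without cross-hybridizing probe sets 5 cell cycle and 2 fasting genes passed, with the mean of probe sets 1 regulator, and with the filter 1 of the 2 interferon-induced genes left and 0 hindlimb genes. In the fast fibre, smooth muscle, forelimb and strain lists the median and the direction of camera's test differed in sign, and the regulators had a median of -0.08 and a mean of 0.02.

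**Figure D3:**
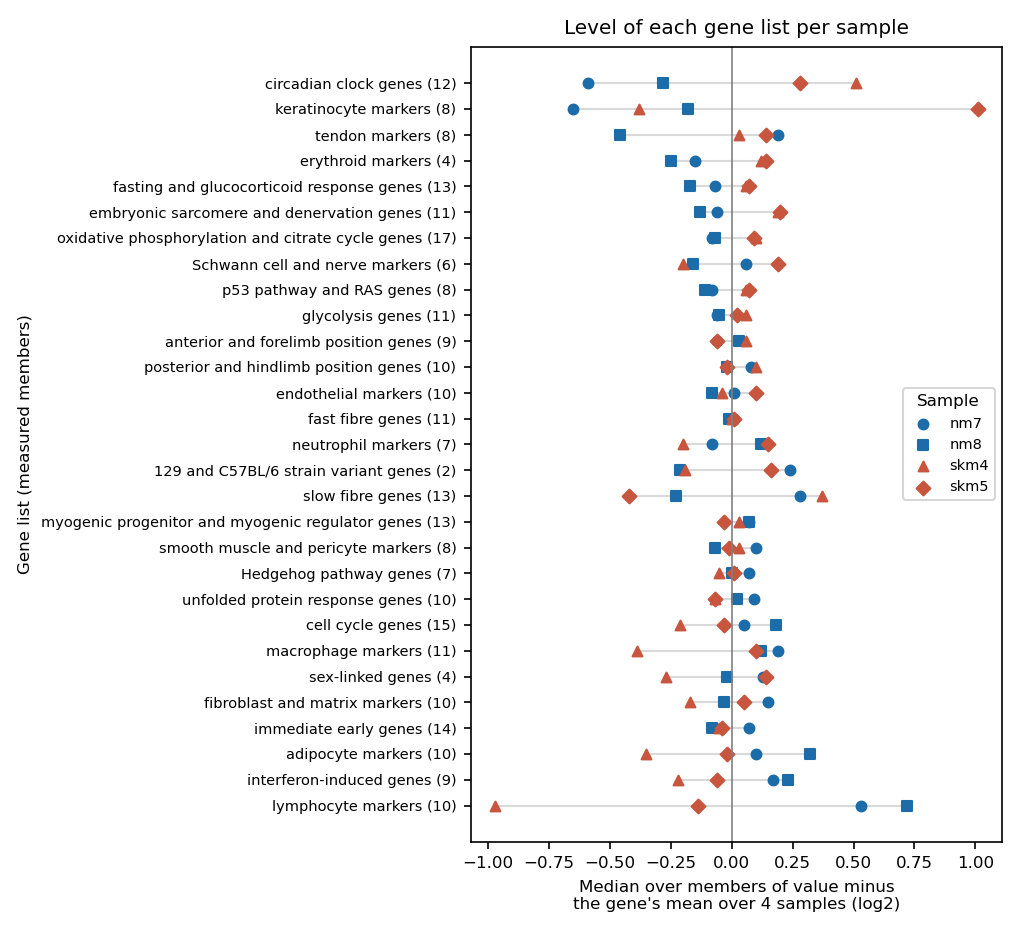
Median over a list's measured members of the log2 value minus the gene's mean over the 4 samples, for each of 29 lists (number of members in brackets), with 1 point per sample and a grey line over the range. Lymphocyte markers run from -0.97 in skm4 to 0.72 in nm8, and clock genes are lower in both nm samples because more of their members rose in skm than fell.

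Control probe sets also differed by prefix, beside the clock, lymphocyte, oxidative and embryonic groups. The 3' probe set of 18S ribosomal RNA read 13.28 in nm7, 13.29 in nm8, 10.87 in skm4 and 11.23 in skm5, a difference of -2.24 (4.71-fold), and the 5' and middle probe sets differed by -1.43 and -1.28. The 3' minus 5' difference of beta-actin, in which a higher value goes with shorter labelled RNA, was 0.62 and 0.56 in nm against -0.45 and -0.44 in skm, and that of Gapdh had means of 0.23 and 0.03. The bacterial spikes went the other way, with means of 2.63 in nm and 3.30 in skm for dap, 2.49 and 2.91 for thr, 1.03 and 1.37 for lys and 0.40 and 0.66 for phe. Each of these spikes was higher in both skm than in both nm samples. Spikes are not muscle RNA, so their difference by prefix was technical. How far such a difference reached the muscle genes was not tested. Across genes, which are not independent replicates, the SD of the log2 differences was 0.268 between nm7 and nm8 and 0.31 between skm4 and skm5, against 0.394 to 0.442 between arrays of different prefix. The labels name no batch for these samples, and a batch that followed the prefix cannot be told apart from it.

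**Figure D4:**
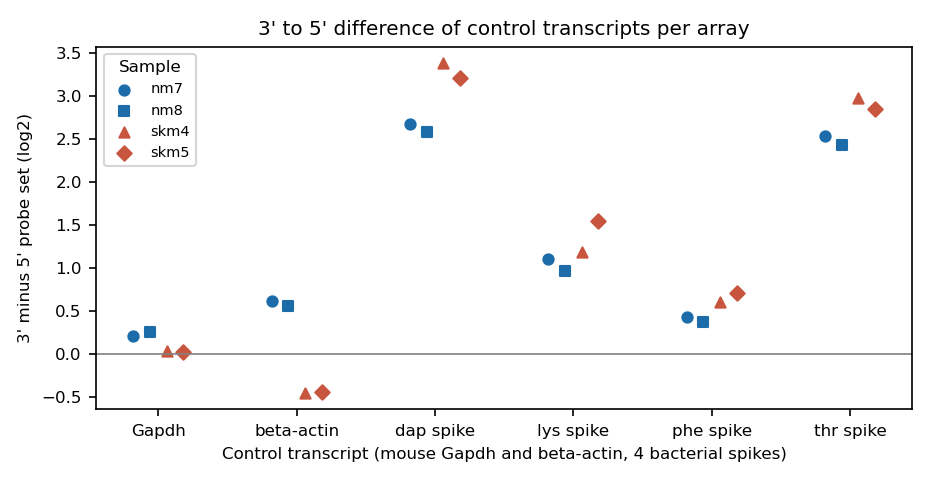
Log2 difference of the 3' and 5' probe sets of 2 mouse transcripts and 4 bacterial spike RNAs in the 4 samples, with 1 point per sample. Beta-actin lies at 0.56 and above in nm and at -0.44 and below in skm, and the dap and thr spikes are higher in skm.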

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

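The tests for the array-wide, lymphoid RNA and leukocyte explanations and the count over splits of the samples were chosen after the results they weigh were seen; the tests on further clock, lymph node and slow fibre genes were written before those genes were looked at. The design names no group among these samples, so no biological explanation was set by it.

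A single sample lay far from the other 3 in 10 of 163 named genes (6.13%) and in 1 of 29 lists, by Dixon's ratio. Chance gives about 5% for unselected genes in samples of 1 kind. The named genes were picked by SD, prefix difference or moderated t, so their share cannot be weighed against that 5%. The lists were fixed in advance, and 1 of 29 lies under 5%, so the list call is no more than chance would give. In skm4, macrophage markers were low (ratio 0.852, centred median -0.39), as was Col5a1, a fibrillar collagen gene, at 10.04 against 10.45 to 10.52 (0.851). Low in the same sample were the Y-linked genes Kdm5d at 7.19 against 7.76 to 7.78 (0.966) and Eif2s3y at 9.67 against 9.88 to 9.93 (0.835). In skm5, Dsp was high at 8.33 against 4.12 to 4.48 (0.915), Ltf, the neutrophil protein lactoferrin, was high at 5.78 against 5.10 to 5.20 (0.853), and Calcr, a receptor of quiescent satellite cells, was low at 5.06 against 5.56 to 5.63 (0.877). In nm7, Sufu, a Hedgehog inhibitor, was high at 7.68 against 7.45 to 7.47 (0.898), as was the heat shock gene Hspa1b at 9.29 against 7.68 to 7.92 (0.851), whose probe set cannot be fully separated from the near-identical Hspa1a. In nm8, Sesn2, a p53 target, was high at 6.96 against 6.33 to 6.44 (0.83), and Comp, a cartilage and tendon matrix protein, was low at 7.51 against 8.48 to 8.64 (0.859).

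An array-wide or labelling difference between the prefixes stays open for the clock genes, since 18S and beta-actin controls differed by prefix as well, and their median absolute difference, at percentile 100 of random lists, restates the pattern and tests no cause. RNA of lymphoid tissue is argued against: the lymphocyte markers' skm5 to skm4 difference was 0.44 of their prefix difference, while that of the clock genes was 0.07. Collection at another time of day is a candidate explanation that stays open: 6 of 6 further clock output genes went the way it needs, among them Wee1 at 0.96 and Tsc22d3 at 0.81, and at least 6 had been set in advance. That number counts Nfil3 at -0.01 ± 0.17, whose skm5 value of 8.87 lay above both nm samples, and without it the 5 others, all without overlap between prefixes, fall short. Time of collection is not in the labels, and a batch that acts on these genes in particular stays open.

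More leukocytes of every kind in nm stay open beside the fall of lymphocyte markers in skm: macrophage and neutrophil markers together had a median of -0.08 (lower bootstrap bound -0.25) where -0.67 would be needed, and without skm5 the macrophage median was -0.47 beside -1.64 for lymphocytes, which falls short too, but neutrophil markers were dim, at 4.56 to 7.43, and macrophage markers, at up to 11.13, could hide a small share. An array-wide or labelling difference between the prefixes stays open as well, since the skm samples' own difference of 0.71 in these markers, at percentile 100 of random lists, lies within a prefix and does not bear on it. Lymph node tissue in the nm samples could be a source, but 7 of 12 further lymph node genes showed the needed order (16.2% of all genes do), short of the 9 set in advance. Their median was -0.73, with Il7r at -1.66 and Ccr7 at -1.09, while Madcam1 at 0.28 and Chst4 at 0.47, dim genes of lymph node venules, went the other way and Glycam1, a venule gene seen beforehand, went with it at 9.69 and 10.14 in nm against 7.77 in skm5 and a dim 4.59 in skm4. Lymph node tissue therefore stays open, and lymphocytes in blood or muscle were not tested.

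The slow fibre spread may come from the part of muscle that was sampled. A further 8 genes of slow and oxidative fibres were read for it, and 4 of them were higher in nm7 than in nm8 and in skm4 than in skm5, against 11 of the 13 listed genes and 21.5% of all genes. This falls between the bounds set in advance, because the further genes had medians of 0.26 and 0.19 with several near 0, so the explanation stays open. Other genes of like level did not share the shift: the upper bound of their median within-prefix difference was 0.05, where the slow list had 0.64. RMA brings the arrays to 1 distribution, which holds such a median near 0 in advance. This comparison therefore cannot weigh an array-wide difference between samples, which stays open. Beta-actin's 3' minus 5' difference was close within each prefix, at 0.62 and 0.56 in nm and -0.45 and -0.44 in skm. Which muscle was taken is not in the labels.

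For the prefix itself, the real split of the samples gave 4 genes and the highest other split 0, so 1 of 3 splits gave as many, and 3 splits are too few for a share under 0.05.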

How the results depend on the processing

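A threshold of 0.10 and fry in either direction were chosen after the data were seen; the other alternatives were planned. The prefix test's 4 genes became 188 with quantile normalization (4 of the first 4 kept), 1026 at or above the median level (3 kept, fewer genes tested), 92 with the mean of probe sets (3 kept), 142 without cross-hybridizing probe sets (4 kept), 1110 with an intensity trend (4 kept), 308 when probe sets were tested and 995 at 0.10; centring gave 4. Leaving out each sample gave 0 to 15, with 0 without nm7, nm8 or skm4; these fits leave a lone sample, assumed to vary like the others. Genes with a range over 1 numbered 291 with the filter and 429 to 546 with a sample left out. Lists called numbered 2 to 7 with a sample left out, 0 with an estimated correlation, 1 with fry and 11 with fry in either direction. The embryonic list had an adjusted p of 0.25 with the filter, 0.054 with the mean of probe sets, 0.062 without cross-hybridizing probe sets, 0.83 with an estimated correlation, 0.099 with fry and 0.017 to 0.082 with a sample left out. The oxidative list had 0.1 with quantile normalization, 0.83 with an estimated correlation and 0.029 to 0.082 with a sample left out. The lymphocyte list had 0.29 with the filter (2 of 10 genes left), 0.91 with an estimated correlation and 0.22 with fry, and kept its call with any sample left out (1.2e-07 to 0.0018). For the rest the cause was not tested. The number of lists of large spread stayed within 11 to 16 under the alternatives run, and no called gene or list reversed. Arrays this few, and values near 14.76 or near the background, limit what could be seen. No paired analysis was possible because the title numbers of the prefixes (7 and 8, 4 and 5) are not shared.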

Other observations

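The count over further fatty acid synthesis genes was written before they were looked at, while the list was chosen after Lep, Acly and Scd1 had been seen to be low in skm, and the set tests on it were added after its values were seen.

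Beyond the adipocyte markers already given, most of a further list of genes that make fatty acids read lower in skm. Of 10 measured, 8 were lower in both skm than in both nm samples and 9 had a negative difference, with a median of -0.57 at percentile 0 of random lists of like level. Fasn, the fatty acid synthase, differed by -0.85 ± 0.22 (SE, n = 2 per prefix), Scd2, a desaturase, by -1.05 ± 0.29, and Srebf1, the transcription factor that drives this programme, by -0.84 ± 0.14 (adjusted p = 0.0608 with limma). Elovl3, an elongase, went the other way at 0.25 ± 0.26, Mlxipl, a glucose-responsive transcription factor, stood at -0.11 ± 0.12, and 0 of the 10 passed over all genes. For the list, camera gave an unadjusted p = 0.00059 at the preset correlation but p = 0.30 with an estimated correlation, and fry gave 0.122. The 8 genes met the number set in advance for a lower fatty acid synthesis programme in skm, which remains a hypothesis. Over all genes, 54.4% had no overlap between the prefixes, counting both directions. Acly itself serves lipid synthesis, and the list was chosen after low values had been seen on these arrays. The count therefore does not explain the low Lep and Acly values. The 18S 3' probe set (-2.24) and the 3' minus 5' difference of beta-actin (0.59 in nm, -0.44 in skm) differ by the same prefix, so an array-wide or labelling difference stays open here too. Whether the programme belongs to muscle fibres or to fat among them was not tested; Fabp4, an abundant fatty acid carrier of adipocytes, differed by -0.01 and Adipoq by -0.56.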
